A study of Canis lupus familiaris with 15 samples.

How the data were processed

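A custom panel of 160 NanoString probes was measured in skin biopsies of 15 dogs, per the labels. The assay counts colour-coded reporters bound to RNA molecules, without an amplification step. Per the labels' protocols, RNA was extracted from archival biopsies with a Qiagen kit for fixed, paraffin-embedded tissue, and the probes were labelled as the manufacturer describes. The values used here are whole counts per probe as deposited by the authors, with 14 ERCC spike-in control rows beside the 160 panel probes. The lowest count was 1. The counting software, any background subtraction and any scaling are not given in the sources used here. In the deposited counts, the column sums differed between dogs and the control rows had not been scaled to one another. The labels number the lesional samples as cases and the healthy samples as leg margins. Each sample was taken as a separate dog, and p-values cover the spread between dogs only if that holds. The labels place 7 dogs in a group with discoid lupus erythematosus (DLE) and 5 in a healthy group sampled at leg margins. There was 1 dog each with chronic cutaneous lupus and suspected systemic lupus (CCLE), with mucocutaneous lupus (MLE) and with pyoderma, a bacterial skin infection. The series text records that the pyoderma dog earlier carried the label DICLE. The labels mark the 5 healthy samples as re-used from an earlier series, and they do not give the body site of the lesions. They give an age for each lesional dog but for no healthy dog, so age could not be compared between the groups.

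Probe accessions were matched without version numbers to a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, used for names alone, and no coordinates are given because the files name no build. Symbols were found for 72 of the 160 probes, and the other 88 are referred to by accession. HPRT1 and RPL13A, the members of the fixed reference gene list on the panel, were left out of the tests, which leaves 158 probes. Probes of near-identical families (IFNA5 with IFNA7, CCL3 with CCL4) were treated as uncertain, since a probe can bind the related transcript.

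The table turned out to hold raw counts. The fixed design named limma on log2 values as the main test and edgeR's quasi-likelihood test for the case of raw counts, so the latter was used. TMM factors were computed over the panel probes, filterByExpr kept 154 probes, and glmQLFit with glmQLFTest compared 7 DLE with 5 healthy dogs, two-sided, without covariates. Benjamini-Hochberg adjusted p-values under 0.05 were called. Normalised counts are counts divided by the TMM-scaled library size, set to the mean of those sizes. The groups, the tests, the gene lists, the rule for named genes and all alternatives but those marked as added were chosen before the data were examined. The named genes were to be the 15 largest rises and 10 largest falls past the threshold, the 3 members of each list with the largest change, for each single dog the 8 probes farthest above and the 4 farthest below the healthy mean with 4 on either side of the DLE mean, and a fixed set of genes of which S100A8 and CD8A matched no probe. Because only 4 of the 15 rises and 5 of the 10 falls taken from all probes had a symbol, the rule was applied to probes with a symbol, a restriction chosen after the values were seen. Where further genes are named, this is said beside them.

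Of 26 gene lists written, the 10 with at least 3 members on the panel were used. They cover interferons and their receptors (no receptor matched a probe), macrophage and monocyte genes, dendritic cell genes, and neutrophil and acute inflammation genes. The others cover Th2, Th1 and Th17 genes, chemokines, keratinocyte markers and melanocyte markers. A list score is the mean over members of log2(normalised count + 1) per dog. Scores were compared by an exact permutation test over all 792 splits of 12 dogs into 7 and 5, two-sided, whose smallest p is 0.00253, with Benjamini-Hochberg adjustment over the 10 lists. Each single dog was compared without a test, by counting the probes of 158 outside the range of a group and at least 2-fold from its mean log2 value. By rank alone a dog of the same population would lie above all 5 healthy dogs for 16.7% of probes and above all 7 DLE dogs for 12.5%, with equal shares below.

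The background limit of a dog was the mean plus 2 SD of its 8 low control rows. Exact Poisson intervals (95%) run from 12.2 to 30.9 for a count of 20, from 81.4 to 122 for 100 and from 939 to 1064 for 1000, and cover counting error only. No 2 columns of a group were duplicates within counting noise (lowest chi-square per degree of freedom 162), which excludes repeated columns only, and each labelled dog was counted as 1 replicate. The edgeR step was tested on simulated data for DLE against healthy dogs, with 40 of 154 probes changed in 20 runs. It recovered 26.5% of 2-fold and 82.7% of 4-fold changes, 5.34% of its calls were false and 0 had the wrong direction. The simulated changes went up and down in equal number and were at most 4-fold, whereas 95 of 154 probes were called in the real comparison. These rates therefore do not carry over to it, nor do they cover the choice of scaling.

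The alternatives were scaling by reference genes, by the panel median or by quantiles (with limma), DESeq2 with its size factors, a pseudocount of 10 for scores, the lowest 25% of probes left out or no filter, all 15 dogs in 1 fit, the CCLE and MLE dogs counted with DLE, an exact permutation test per probe, robust limma, list medians, fry for lists, the replicate number as a block and each dog left out in turn. Alternatives added after seeing the data were scaling by the 6 highest spike-in control rows of each dog, limma on log2(normalised count + 1), the most extreme scaling factors (DLE 3 and healthy 1) left out together, and lupus (DLE, CCLE, MLE) against control dogs (healthy, pyoderma) with the control row set as a block. For list scores that block was an additive fit with a two-sided exact permutation over the 54 choices of 1 control dog in set A and 1 lupus dog in set B. The 6 scalings named in the results are TMM, reference gene, panel median, quantile, spike-in and DESeq2. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.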

Results

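Expression of 160 panel probes was counted in skin of 7 dogs with discoid lupus (DLE), 5 healthy dogs and 3 dogs with other diagnoses (CCLE, MLE and pyoderma). Counts summed over the panel ranged from 209889 in healthy dog 1 to 675018 in healthy dog 3, and from 495839 to 587169 in the DLE dogs. The 14 spike-in control rows held from 7.87% to 33.3% of a dog's counts, and the background limit lay between 13.6 and 30.0 counts. The control share was 33.3%, 19.6%, 8.04%, 22.4% and 22.9% in healthy dogs 1 to 5, against 7.87% to 15.4% in the DLE dogs. In these healthy dogs 103, 105, 148, 116 and 114 of the 160 probes passed the background limit, against 126 to 151 in the DLE dogs. Most healthy dogs thus had a weaker panel signal, which is confounded with the main comparison and whose cause was not tested. Different control rows were high in different dogs. The row ERCC_00019.1 had a median count of 64230.5 in the healthy and CCLE dogs (6 dogs, set B) and of 11 in the DLE, MLE and pyoderma dogs (9 dogs, set A), and ERCC_00117.1 had medians of 14 and 51830. Every DLE dog was in set A and every healthy dog in set B, so this difference is confounded with the main comparison. Values with the set as a block are printed for the calls described and for the lists. Those values compare the 9 lupus dogs with the 6 control dogs. In them only the CCLE dog (in set B) and the pyoderma dog (in set A) separate disease from set. The pyoderma dog is itself a lesion and earlier carried the label DICLE. A change that it shares with the lupus dogs shrinks with the block even without a set effect.

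The comparison of DLE with healthy skin asked which panel genes differ in discoid lupus lesions. Among genes with a symbol, the chemokines CXCL10 and CCL5 and the B cell gene MS4A1 had the largest rises in DLE skin. CXCL10, an interferon-induced chemokine that draws T cells, averaged 8510 ± 7340 normalised counts (SD, n = 7) against 67.3 ± 31.4 in healthy skin (n = 5), a log2 change of 6.98 ± 0.91 (SE, edgeR adjusted p = 3.18e-05). CCL5, which attracts T and NK cells, averaged 3338 ± 1718 against 65.7 ± 37.7 (log2 5.67 ± 0.60, adjusted p = 7.42e-06). MS4A1, which encodes the B cell surface protein CD20, averaged 196 ± 87.1 against 18.4 ± 2.87 (log2 3.40 ± 0.41, adjusted p = 1.69e-05). CD40LG, the ligand on activated helper T cells that stimulates B cells, rose by log2 1.89, FOXP3, the transcription factor of regulatory T cells, rose 4.96-fold, and KLRD1, a receptor chain of NK and cytotoxic T cells, rose 3.73-fold. SELPLG, the leukocyte ligand of selectins, rose 5.36-fold and CCL19, which guides T cells and dendritic cells through the receptor CCR7, rose 5.40-fold. For each of these 8 genes all 7 DLE dogs lay above all 5 healthy dogs, and the rise was called under all 6 scalings and with the set as a block. The blocked log2 changes were 3.75 for CXCL10, 3.52 for CCL5, 4.28 for MS4A1, 2.62 for CD40LG, 2.10 for FOXP3, 1.53 for KLRD1, 2.04 for SELPLG and 2.06 for CCL19.

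TNF and IFNG also rose in DLE skin. TNF, a cytokine of macrophages and T cells, averaged 215 ± 52.7 normalised counts against 61.4 ± 20.5 (log2 1.81 ± 0.29, edgeR adjusted p = 0.000176; 1.53 with the set as a block). IFNG, the interferon of T and NK cells, averaged 95.8 ± 63.7 against 19.3 ± 4.20 (log2 2.31 ± 0.44, edgeR adjusted p = 0.000566), but its blocked change was 0.97 (adjusted p = 0.159). The call also ended with the set as a block for CEACAM1, a cell adhesion molecule (log2 2.0, blocked 0.78), PPBP, a platelet chemokine (1.85, blocked 0.84), CCL4, which attracts monocytes and T cells (1.82, blocked 0.92), and CD86, a costimulatory protein of antigen-presenting cells (1.53, blocked 0.86). CCL28, an epithelial chemokine, rose on average (log2 3.36 ± 1.02, edgeR adjusted p = 0.0102), with wide spread between DLE dogs (238 ± 331 against 23.1 ± 4.64 normalised counts). Its call ended in the tests on log2 counts (limma, robust limma and the permutation test, each 1.95, and limma with quantile scaling, 1.57), with the replicate block (2.15) and with the set as a block (0.56). Leaving out DLE dog 2 moved it to 2.40, and leaving out healthy dog 5 moved CCL4 to 2.60. The call of CCL4 also ended with the replicate block (1.92). CD40LG, IFNG, CCL28, MS4A1 and FOXP3 lay at the background limit in most healthy dogs, so their healthy level is an upper bound. CCL3, a chemokine of monocytes and T cells, rose by log2 1.26, but its blocked change was -0.19 (edgeR adjusted p = 0.834). Its call also ended under panel median (0.58) and quantile scaling (0.43) and without any 1 of DLE dogs 2 and 4 and healthy dogs 1 to 4 (1.01 to 1.24). The probes CCL3 and CCL4 are uncertain as to which transcript they count.

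Among the genes that fell in DLE skin were the chemokines CCL27 and CXCL12 and the nuclear receptor PPARG. CCL27, a keratinocyte chemokine that draws skin-homing T cells, averaged 27.9 ± 8.83 normalised counts in DLE dogs (n = 7) against 139 ± 39.97 in healthy dogs (n = 5), a change of log2 -2.33 ± 0.29 (edgeR adjusted p = 2.04e-05). CXCL12, a stromal chemokine, averaged 2060 ± 946 against 8186 ± 1362 (log2 -1.99 ± 0.31, adjusted p = 0.000155). PPARG, a nuclear receptor of fat and sebaceous cells, averaged 179 ± 180 against 1350 ± 1219 (log2 -2.91 ± 0.63, adjusted p = 0.00129), a change that ranged from -3.59 (without DLE dog 6) to -2.23 (without healthy dog 5) with 1 dog left out. CCL24, an eosinophil chemokine, fell 7.38-fold. CYP1B1, a cytochrome P450 enzyme, fell 3.69-fold, TACR1, the receptor of substance P, fell 3.54-fold and ADRB1, the beta-1 adrenergic receptor, fell 5.76-fold. The interferon alpha probe IFNA5 fell 12.5-fold and lay below the background limit in all 7 DLE dogs. Its DLE level is therefore an upper bound, as is that of ADRB1 in all but 1 DLE dog. In healthy dogs 1 to 5 IFNA5 stood at 122.7, 2.645, 241.8, 212.3 and 31.3 normalised counts, above background in 3 of them. Healthy dog 2 lay below every DLE dog (lowest 4.898), so the groups overlapped. These 8 falls were called under all 6 scalings, yet with the set as a block none was (edgeR adjusted p from 0.0883 for CCL27 to 0.608 for ADRB1). The blocked log2 changes were -2.13 for IFNA5, -1.62 for PPARG, -1.55 for TACR1 and -1.35 for CCL27. Those of CCL24, CXCL12, CYP1B1 and ADRB1 were -1.28, -0.92, -0.65 and -0.42. The call of IFNA5 also ended in the exact permutation test per probe (log2 -2.57). IFNA7 (log2 -1.70) and CD163, a scavenger receptor of macrophages (log2 -1.41), fell under TMM but not under reference gene scaling (-1.06 and -0.75), nor CD163 under spike-in scaling (-1.05). With the set as a block CD163 was called (log2 -1.78, edgeR adjusted p = 0.00993) and IFNA7 was not (-1.25, adjusted p = 0.299), and the interferon alpha probes cannot be assigned to single family members.

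**Figure D1:**
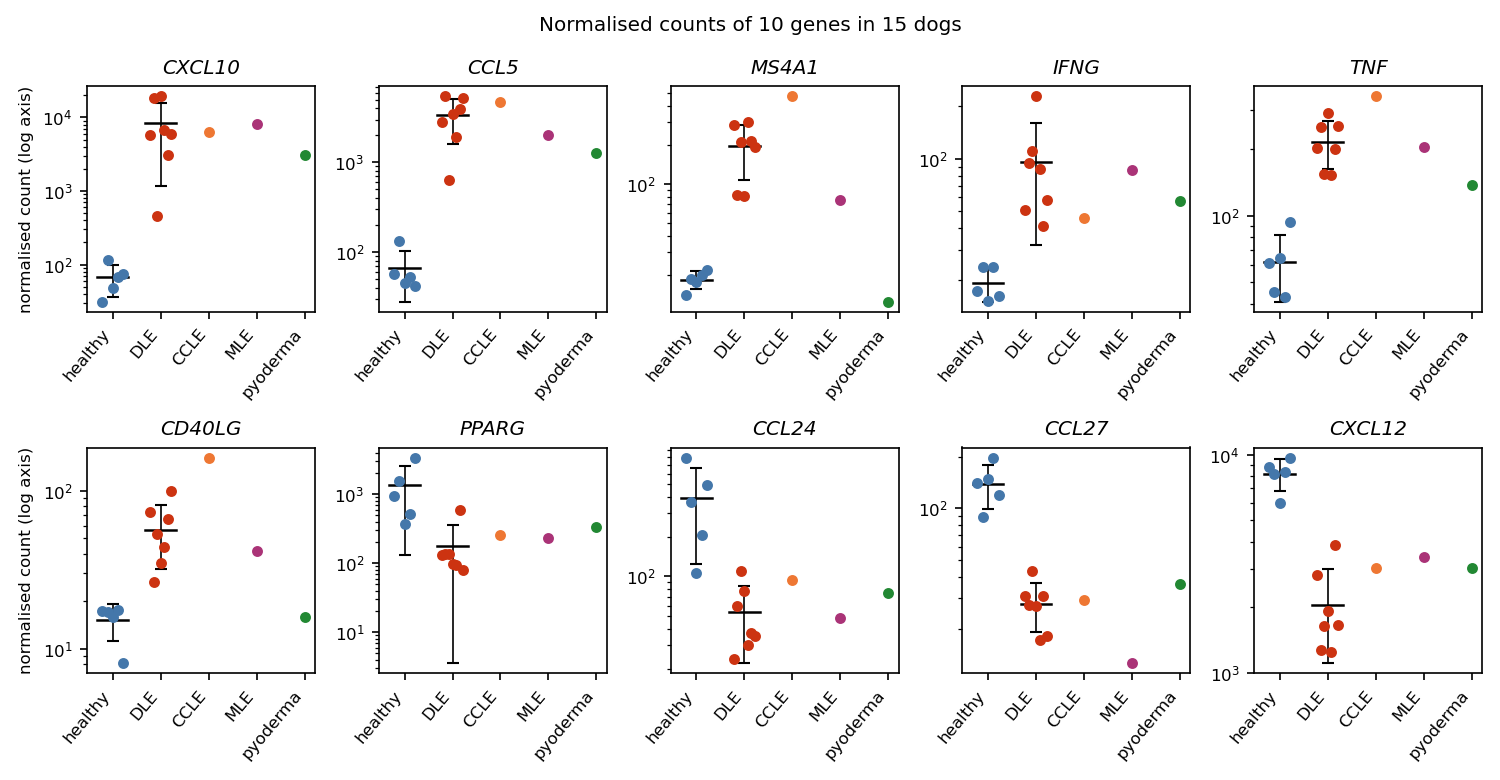
Normalised counts (log axis) of 10 genes by diagnosis, 1 point per dog, with the mean as a line and the SD as error bars for the 7 DLE and 5 healthy dogs. For CXCL10, CCL5, MS4A1, IFNG, TNF and CD40LG every DLE dog lies above every healthy dog. MS4A1 in the pyoderma dog (12.5) lies below all healthy dogs, but it and most healthy dogs are at background.

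In all, 95 of 154 probes were called, 58 higher and 37 lower in DLE dogs, of which 19 and 20 had a symbol. For 40 of the higher and 18 of the lower calls the groups did not overlap, which chance gives for 0.253% of probes. Among probes without a symbol, XM_003434905.4 (log2 6.66) and NM_001002987.2 (5.25) had the largest rises and XM_005615400.3 (-3.33) and XM_538269.6 (-2.67) the largest falls. With the set as a block XM_003434905.4 was called (log2 2.84, edgeR adjusted p = 0.0489), whereas NM_001002987.2 (3.55), XM_005615400.3 (-1.56) and XM_538269.6 (-3.81) were not. Leaving out healthy dog 3 moved XM_003434905.4 to 8.64, and leaving out DLE dog 6 moved XM_005615400.3 to -4.78. Scaling moved the split of calls, which was 61.1% higher under TMM, 82.8% (82 higher, 17 lower) under reference gene scaling, 77.0% (57 and 17) under spike-in scaling, 46.4% (45 and 52) under quantile scaling and 39.8% (43 and 65) under panel median scaling. The median log2 change of all probes was 0.42 under TMM, 1.06 with reference genes, 0.72 with spike-ins, 0.11 with DESeq2, -0.14 with quantiles and -0.26 with the panel median. Relative to the TMM median, CXCL10 changed by 6.56, CXCL12 by -2.41 and CCL27 by -2.75. Under TMM scaling the reference genes also differed between the groups. This does not tell a change in these genes from an offset of the scaling. RPL13A, a ribosomal protein gene, averaged 15330 ± 3412 normalised counts in 7 DLE dogs against 31090 ± 8566 in 5 healthy dogs (exact permutation p = 0.00253), and HPRT1, an enzyme of purine salvage, 614 ± 80.4 against 811 ± 134 (exact p = 0.00505). Calls under all 6 scalings numbered 41 higher and 16 lower. With the set as a block 40 probes were called, 34 higher and 6 lower, and 34 and 4 of these were among the calls of the main comparison. These blocked calls rest on the CCLE and pyoderma dogs. With any other dog of set B in the place of the CCLE dog at most 1 probe was called, and with another dog of set A in the place of the pyoderma dog 0 to 41 were.

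**Figure D2:**
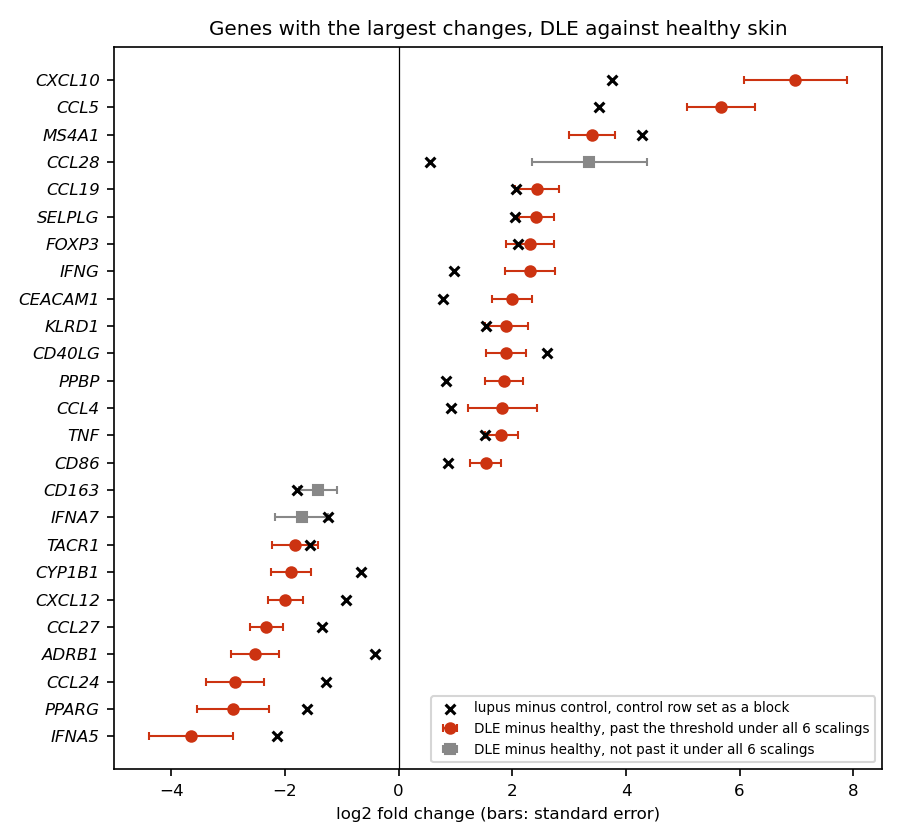
Log2 fold change of DLE against healthy skin (x axis) for the 15 named genes with the largest rises and the 10 with the largest falls, with SE bars, and crosses for lupus minus control with the control row set as a block. CXCL10 (6.98) and CCL5 (5.67) lead the rises, and the crosses of the falls lie closer to 0 than their points for all named falls but CD163.

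Among the lists, Th1 genes rose. Their score was 1.74 higher in DLE dogs on the log2 scale (exact permutation p = 0.00253, the smallest possible, adjusted p = 0.0253), all 7 DLE dogs lay above all healthy dogs, and fry gave an adjusted p of 0.000147. Of the 3 measured Th1 genes 3 rose, also adjusted over the list alone: IFNG, TNF and IL12B, a subunit of interleukins 12 and 23 (log2 1.41, called under TMM but not under panel median (0.65) or quantile scaling (0.44), and blocked 1.17). The blocked Th1 score was 1.18 higher in lupus dogs (exact permutation within the sets p = 0.0185, the smallest that 54 choices can give, adjusted p = 0.185), a test in which 1 list alone cannot pass the threshold. Of the written type I interferon-stimulated genes only CXCL10 matched a probe, so that list was not scored. In the list of interferons and their receptors 5 interferons and no receptor matched a probe. This list did not pass the test (-0.69, exact p = 0.116, adjusted p = 0.242). IFNG rose, IFNA5, IFNA7 and IFNB1 fell and 1 was not called, and adjusted over the list alone the counts were the same. IFNB1 (log2 -1.32) lay at background in all but 1 DLE dog, and its call ended under reference gene (-0.61) and spike-in scaling (-1.15) and with the set as a block (-0.57). The median over members gave -1.11 with an adjusted p of 0.0253. Of the 21 chemokines 6 rose (CXCL10, CCL5, CCL28, CCL19, CCL4, CCL3), 4 fell (CCL24, CCL27, CXCL12, CCL21) and 11 were not called, and adjusted over the list alone 6 rose and 4 fell. The call of CCL21 (log2 -1.15) ended under reference gene (-0.54) and spike-in scaling (-0.98), with the replicate block (-0.97) and with the set as a block (-0.76). The chemokine score differed by 0.43 (exact p = 0.111, adjusted p = 0.242), with the opposite sign under panel median scaling (-0.25).

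The other lists did not pass the test. Type 2 genes scored -0.68 (exact p = 0.0631, adjusted p = 0.242): CCL24 and IL4 fell and 3 did not pass, with 1 fall adjusted over the list alone, and IL4 (log2 -0.84) lay at background in both groups. Its call ended under reference gene (-0.08) and spike-in scaling (-0.48), in the tests on log2 counts (-0.71, with quantile scaling -0.73), with the replicate block (-0.58), with the set as a block (0.06) and without 9 of the 12 dogs in turn. Th17 genes scored 0.05 (exact p = 1), with no member called of 4, none adjusted over the list alone, and -0.61 under panel median scaling. DLE dog 4 set the group means of IL17A, CCL20 and CCL17: its raw IL17A count was 120 against 2 to 13 in the other DLE dogs, and without it the log2 changes of CCL20 and CCL17 moved from 1.65 to 0.51 and from 1.71 to -0.23. Macrophage and monocyte genes scored -0.27 (exact p = 0.447, adjusted p = 0.639; 0.43 under reference gene scaling), with CD86 up, CD163 down and CCL2 at log2 -1.05 not called, while adjusted over the list alone 1 rose and 2 fell. CCL2 was called lower under panel median scaling (-1.75), with DESeq2 (-1.38) and without any 1 of DLE dogs 2 and 4 and healthy dogs 1 and 4 (-1.24 to -1.20). Dendritic cell genes scored 0.49 (exact p = 0.149, adjusted p = 0.248; -0.20 under panel median scaling). Of these CCL19 rose, CCL21 fell and CCL17 was not called, with the same counts adjusted over the list alone. Neutrophil and acute inflammation genes scored 0.23 (exact p = 0.722, adjusted p = 0.847; -0.47 under panel median scaling), where TNF rose and CXCL8 (log2 0.01), IL1B (0.86) and IL6 (-1.44) were not called, with 1 rise adjusted over the list alone. IL6 was called lower under panel median (-1.98) and quantile scaling (-2.51) and stood at -0.59 without healthy dog 5, and IL1B was called higher under reference gene scaling (1.63).

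Skin cell marker lists did not pass the test either. Keratinocyte markers scored 0.50 (exact p = 0.121, adjusted p = 0.242; -0.20 under panel median scaling). KRT14, a keratin of basal keratinocytes, rose by log2 1.32 (edgeR adjusted p = 0.0243), while its blocked change was -0.03 and its call also ended under panel median (0.66) and quantile scaling (0.85) and without any 1 of healthy dogs 2, 3 and 5. KRT1 (0.80) and KRT5 (0.41) were not called, with 1 rise adjusted over the list alone. KRT1 ranged from 0.13 to 1.02 with 1 dog left out. Melanocyte markers scored -0.23 (exact p = 0.763, adjusted p = 0.847; 0.45 under reference gene scaling). DCT (log2 0.19), TYR (-0.13) and MC1R (0.01), genes of pigment synthesis, were not called, nor was any adjusted over the list alone. The blocked scores of the 9 lists other than Th1 were -0.61 for interferons, -0.60 for macrophage, 0.93 for dendritic cell, -0.59 for neutrophil, -0.12 for type 2 and -0.44 for Th17 genes, 0.04 for chemokines and -0.21 and 0.44 for keratinocyte and melanocyte markers.

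The dog with CCLE was set beside the healthy and DLE dogs to see where a chronic lupus lesion with suspected systemic disease lies. In this and the other single dogs, log2 values are differences from the mean log2 count or score of the group named, not from the edge of its range. MS4A1, CD40LG, CCL19, SELPLG, FOXP3 and TNF lay above the ranges of both groups. MS4A1 stood at 474 normalised counts, against 18.4 ± 2.87 (SD) in 5 healthy and 196 ± 87.1 in 7 DLE dogs. CD40LG stood at 161 (DLE mean 56.7 ± 24.8) and CCL19 at 2942 (DLE mean 1161 ± 583). KLRD1 (118) lay inside the DLE range. CXCL10 (6327) and CCL5 (4715) lay above the healthy and inside the DLE range, at log2 6.66 and 6.28 over the healthy mean, as did IFNG (45.4, log2 1.22). SELPLG lay 3.60, FOXP3 3.25 and TNF 2.54 over the healthy mean on the log2 scale. Below the healthy range lay IL6 (30.3 normalised counts, log2 -4.05), CCL13 (-2.96), TACR1 (-2.60) and CCL27 (-2.16). Against DLE, KLK7, a protease of the outer epidermis (5010, log2 2.33), and ADRB1 (81.4, log2 2.22) lay above the range, but both lay inside the healthy range. IL6 (-1.99) and PPBP (-1.58) lay below the DLE range, as did IFNK and IL17A, both at background. CXCL8 (350) and IL13 (36.9) lay inside both ranges. The dendritic cell score was above both ranges, 1.77 over the healthy mean, and the Th17 score below both, at -1.05 from the healthy mean. The 3 members of the dendritic cell list are all chemokines. In this dog CCL19 and CCL17 (225.3) lay above the healthy range, but CCL21 (942.7) lay below it. In number, 53 probes lay above and 37 below the healthy range by 2-fold, against 18 and 14 for the DLE range. The CCLE dog shares its control row set with the healthy dogs, and 1 dog allows no test.

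The dog with MLE was likewise set beside both groups. CXCL8 and IL1B lay above the ranges of both groups. CXCL8, the main neutrophil chemokine, stood at 20700 normalised counts, against 2978 ± 2469 (SD) in 5 healthy dogs and 3007 ± 1916 in 7 DLE dogs. IL1B, an inflammatory cytokine, stood at 710 against 71.1 ± 45.6 and 130 ± 98.6. IL6 (113) lay below the healthy and inside the DLE range, and TNF (204) lay above the healthy and inside the DLE range. The neutrophil and acute inflammation score lay above both ranges, 1.71 over the healthy mean and 1.48 over the DLE mean. CXCL10 (8073, log2 7.01), CCL5 (5.06), CCL28 (3.41), IL17A (60.8 normalised counts, 2.94), CCL4 (2.90) and CEACAM1 (2.81) lay above the healthy range, as did IFNG (2.14) and MS4A1 (1.99), whereas MS4A1 (75.6) lay below the DLE range. COL1A1, a collagen of the dermis (log2 1.76), and CCL25 (1.15) were above the DLE range but inside the healthy range. COL1A1 was also above the DLE range in the CCLE and pyoderma dogs (83190 and 64580 normalised counts, against 100900 in the MLE dog). DCT (at background, log2 -3.73), CCL27 (at background, -3.32), CCL24 (-2.68) and MS4A2, a chain of the IgE receptor of mast cells (-2.88), were below the healthy range. PPBP (-3.35), MS4A2 (-2.20), IL21 (-1.84) and TYR (-1.73) were below the DLE range, all but MS4A2 at background. IL13 lay inside both. In number, 53 probes lay above and 45 below the healthy range by 2-fold, against 7 and 18 for the DLE range, with no test possible for 1 dog.

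The dog with pyoderma, which earlier carried the label DICLE, gives a lesion without a lupus diagnosis in its present label. CXCL10 and CCL5 were above the healthy range in it too, but MS4A1 and CD40LG were not. CXCL10 stood at 3130 normalised counts (log2 5.65 over the mean of 5 healthy dogs) and CCL5 at 1282 (4.41), and CCL28 (3.77), CCL20 (2.22), CCL3 (2.11), CCL4 (1.88), CCL19 (1.87), SELPLG (1.78) and IFNG (1.54) were also above the healthy range. MS4A1 stood at 12.5 and CD40LG at 15.9, at background, both below the range of the 7 DLE dogs (log2 -3.71 and -1.65 from the DLE mean). MS4A1 also lay below the healthy range (log2 -0.51 from the healthy mean), which turned to 0.50 over the healthy mean under reference gene scaling. This count and those of most healthy dogs were at background, so their order carries no weight. IL13, a type 2 cytokine, stood at 107 against 48.4 ± 20.9 (SD) in healthy and 37.5 ± 18.5 in DLE dogs, above both ranges. KLK7 (log2 1.82), CD163 (1.80) and MS4A2 (1.41) were above the DLE range, of which KLK7 and CD163 lay inside the healthy range and MS4A2 above it. DCT and IL4 (both at background) were below both ranges, and IL6 (-2.13) and CCL24 (-2.05) below the healthy range. CXCL8 (3198) and IL17A (7.96, at background) lay inside both. The Th1 score lay above the healthy range (1.19 over its mean) and below the DLE range (-0.54 from its mean). In number, 43 probes lay above and 32 below the healthy range by 2-fold (49 in all under spike-in scaling, not 75), against 11 and 20 for the DLE range, with no test possible for 1 dog.

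Of the 58 probes that rose in DLE, 52 lay above the healthy range in the CCLE dog, 54 in the MLE dog and 51 in the pyoderma dog. Independent lists would share 22.2, 25.6 and 25.2. Of the 37 that fell, 32, 31 and 29 lay below it (independent lists 12.7, 12.7 and 9.61). All these comparisons share the healthy dogs. A healthy dog left out of the calls lay above the other 4 for 7 to 15 of the raised and below them for 2 to 16 of the lowered probes. For every probe some healthy dog must be highest and some lowest, so such counts arise from ranks alone. They do not show how much of the overlap comes from the shared controls, and part of it may.

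**Figure D3:**
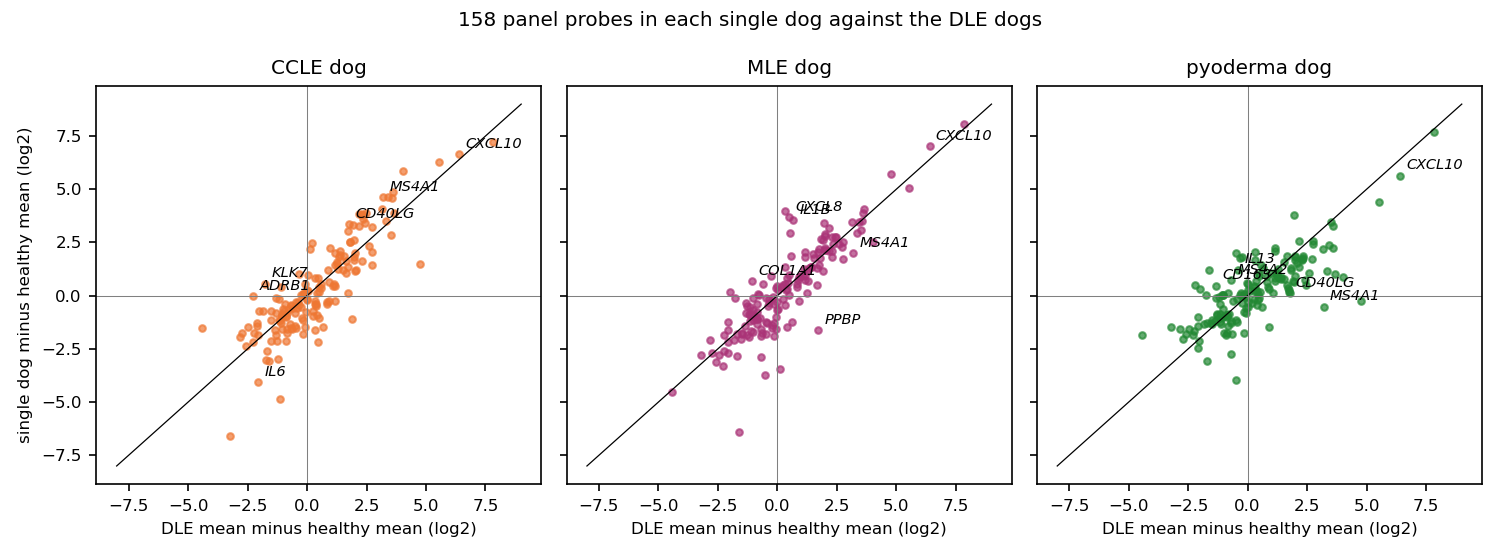
Log2 difference from the healthy mean in each single dog (y axis) against that of the DLE mean (x axis) for 158 probes, 1 point per probe, with the line of equality. CXCL10 lies near the line in all 3 panels, CXCL8 and IL1B lie far above it in the MLE dog, and MS4A1 and CD40LG lie below it in the pyoderma dog.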

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

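The 8 tests of explanations given here were chosen only after the results they weigh had been seen. A control row outside the main measurement stood far above background in 1 set of dogs each time: ERCC_00019.1 had a median count of 64230.5 in the healthy and CCLE dogs (11 in the others) and ERCC_00117.1 one of 51830 in the DLE, MLE and pyoderma dogs (14 in the others). Single dogs lay far from the rest of their group in 12 of 108 tests, of which chance gives about 1 in 20. In DLE dog 3 the IFNA7 probe stood at 57.2 normalised counts (nearest other DLE dog 21.97), the interferon score at 5.06 (4.27), the keratinocyte score at 16.3 (15.1) and the TMM factor at 0.445 (0.975). In DLE dog 4 ADRB1 stood at 8.16 (15.8), CCL20 at 1654 (266) and IL17A at 98.0 (13.0). In DLE dog 6 PPARG stood at 583 (135) and CXCL8 at 277 (1679). In the healthy group CCL5 stood at 132 in dog 2 (56.6), PPBP at 39.7 in dog 2 (48.8) and CD40LG at 8.17 in dog 5 (15.8).

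The first pattern is the rise of 58 probes in DLE skin, led among probes with a symbol by CXCL10, CCL5 and MS4A1. The real split of the 12 dogs called 95 probes, and 1 of 100 drawn splits, the real one, gave as many (highest other 29). This bounds chance at about 1 in 100, with 792 splits possible. The real split is also that of the control row sets, so the test does not tell disease from set. With the control row set as a block, 34 of the 58 were still called and 54 kept their sign (median log2 1.46, against 2.19 without the block), and 41 were called under all 6 scalings, which argues against the separate sets or the scaling between dogs as the whole cause, but leaves the sets open for the other 24 and the scaling for the other 17. The blocked fit called 40 probes and leans on the CCLE and pyoderma dogs: the CCLE dog's median over the raised probes was 2.08 above the healthy mean (left-out healthy dogs at most 0.13), 2 of 54 choices of 1 control dog in set A and 1 lupus dog in set B gave as many calls, the other giving 41 with DLE dog 3 as the control and CCLE as the lupus dog, no choice of another dog in set B gave more than 1, and the 9 choices with CCLE gave 0 to 41. The pyoderma dog, without a lupus diagnosis in its present label but earlier labelled DICLE, lay above the healthy range for 51 of the 58. Lesional inflammation of any kind therefore stays open beside lupus with 1 such dog. A change that this dog shares shrinks with the block without any set effect. The 24 lost calls therefore do not tell a set effect from a shared lesional change. Body site (leg in healthy dogs, not given for lesions) and age (not given for healthy dogs) also stay open and were not tested. The same holds for the weaker panel signal of most healthy dogs.

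The second pattern is the fall of 37 probes, led among probes with a symbol by IFNA5, PPARG and CCL24. An equal dilution of all resident skin RNA by infiltrating cells was weighed on fallen probes chosen without 1 DLE and 1 healthy dog. In those 2 dogs the mean of these probes was taken from the keratinocyte score. A factor per dog cannot move this gap, and an equal dilution leaves its difference between the dogs at 0. The gap was higher in the DLE dog in 35 of 35 pairs (mean log2 2.02, lowest 0.99). The 3 keratinocyte markers thus did not fall with these probes. However, their score was already known to be higher in DLE dogs (0.50), and KRT14 was itself called higher. The pairs share dogs, and each also sets a dog of set A against 1 of set B. The gap therefore does not decide whether equal dilution was the whole cause. With the control row set as a block, 4 of the 37 were still called and 36 kept their sign, and of the 33 calls that ended 32 had a smaller change and 33 a larger SE (medians of the 37 in edgeR: log2 -1.41 ± 0.31 SE without and -0.76 ± 0.49 with the block). The CCLE dog, in the set of the healthy dogs, had a median of -1.41 from the healthy mean over the fallen probes (DLE dogs -1.36) and lay below the healthy range for 32 of them (left-out healthy dogs at most -0.30), which goes against the set as the cause, but 1 dog excludes nothing, so for the other 33 the set and the disease cannot be told apart. The pyoderma dog, the only control in set A, lay below the healthy range for 29 of the 37. A change that this dog shares shrinks with the block without any set effect. Under all 6 scalings 16 stayed called, and for the other 21 scaling and disease cannot be told apart. Body site, age, the weaker panel signal of most healthy dogs and a change in the makeup of resident cells stay open and were not tested.

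The third pattern is the exchange of high control rows between the sets. If the 2 sets had assigned panel rows to different probes, the profiles of DLE and healthy dogs over the 160 probes would not correlate, but Spearman's correlation across probes of the mean log2 counts was 0.767 (highest of 1000 row permutations 0.264). The CCLE dog, in the set of the healthy dogs, correlated at 0.92 with the DLE mean and at 0.694 with the healthy mean. These correlations argue against misassigned panel rows as a whole, though probes are not independent replicates and a few such rows would not show. ERCC_00019.1 ranged from 42128 to 75284 counts in set B and from 3 to 16 in set A, and the 6 high rows of each set were low in the other. The 2 sets thus differ in their control rows, and spike-in scaling compares different rows between them. Whether each set was a separate run of the assay stays open, and no biological explanation was tested.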

How the results depend on the processing

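Scaling by spike-in rows, limma on log2 counts, the fit without DLE 3 and healthy 1 and the control row set as a block were chosen only after the results were seen, and the cause of the changes below was not tested. The count of 95 calls stayed between 74 and 108 under the other scalings, tests, filters and groupings and between 91 and 98 with each dog left out, but was 40 with the set as a block. Outside the count, lists and single-dog counts, values named in the text kept direction and side of the threshold in 1634 alternatives, lost the call in 102, gained one in 18, turned in 73 and, without a test, moved by over 1 SD in 94. The replicate numbers do not pair the dogs: correlations of same-numbered deviations were 0.0551, 0.16, 0.172, -0.141 and 0.14, only numbers 2 and 5 matched their own number best, and the replicate block gave 85 calls (52 higher, 33 lower). It gave 0.13 for TYR, -0.14 for DCT and -0.054 for IL10. The genes whose direction turned were not called but for IL4, KRT14, CCL3 and MS4A2, and MS4A1 in the pyoderma dog. With the set as a block the log2 changes were 0.062 for IL4, -0.031 for KRT14, -0.19 for CCL3, -0.13 for IL10, -0.60 for IL1B, -0.061 for CCL20, -0.026 for KRT1, -0.063 for KRT5, 0.16 for TYR, -0.009 for MC1R and -1.15 for CXCL8. Quantile scaling gave -0.51 for CCL17, -0.004 for IL1B, -0.013 for KRT1, -0.13 for KRT5, -0.998 for DCT, -0.66 for MC1R, -0.70 for IL10 and -0.12 for CD38. Panel median scaling gave -0.23 for KRT5, -0.56 for DCT, -0.64 for MC1R, -0.58 for CXCL8, -0.66 for IL10, -0.41 for CD38 and -0.19 for HIF1A. Reference gene scaling gave 0.51 for TYR, 0.32 for IL13 and 0.068 for MS4A2, and 0.50 for MS4A1 in the pyoderma dog against healthy dogs. DESeq2 gave -0.45 for CCL17, -0.12 for IL17A, -0.21 for IL10, -0.067 for DCT, -0.22 for MC1R and -0.28 for CXCL8. On log2 counts (exact permutation, limma and robust limma alike) KRT1 was at -0.01, DCT at -0.50 and MC1R at -0.048. With CCLE and MLE counted as DLE, DCT was at -0.10 and MC1R at -0.17. Without DLE 3 and healthy 1, DCT was at -0.10, MC1R at -0.16 and CXCL8 at -0.40. With each dog left out, CCL17 ranged from -0.23 (without DLE 4) to 1.92, DCT from -0.30 (turned without DLE 1, DLE 4, healthy 1 or healthy 2) to 1.10, TYR from -0.42 to 0.42 (without healthy 3), MC1R from -0.24 (without DLE 1) to 0.25, IL10 from -0.015 (turned without DLE 1, DLE 6 or healthy 3) to 0.15 and CXCL8 from -0.29 (without healthy 1) to 0.31. KRT14 lost its call without healthy 2 (1.16), healthy 3 (1.27) or healthy 5 (1.29), IL4 without any dog other than DLE 3, DLE 4 or healthy 2, and CCL20 gained one without DLE 7 (1.84). Genes not called were also called under reference gene scaling (CCL17 2.63, CCL20 2.45), spike-in scaling (IL17A 2.48) and panel median and quantile scaling (IL13 -1.10 and -1.07). IL17A without DLE 4 fell to the low-count filter and has no value. Of the lists, only Th1 was called, and its score ranged from 1.57 to 1.82 with each dog left out. Without any 1 healthy dog its adjusted p was 0.0606, and without DLE 3 and healthy 1 (1.74) it was 0.0952, which are the smallest that so few dogs allow, as is its 0.185 with the set as a block (1.18). Lists that gained a call were interferons (-1.11) and dendritic cell genes (1.89) as medians over members, dendritic cell genes (1.18), chemokines (1.12) and keratinocyte markers (1.2) under reference gene scaling, and macrophage (-0.97) and Th2 genes (-1.34) under the panel median. The set as a block turned neutrophil genes (-0.59), Th17 genes (-0.44), keratinocyte markers (-0.21) and melanocyte markers (0.44). Panel median scaling turned dendritic cell genes (-0.20), neutrophil genes (-0.47), Th17 genes (-0.61), chemokines (-0.25) and keratinocyte markers (-0.20). Reference gene scaling turned macrophage genes (0.43) and melanocyte markers (0.45), as did spike-in scaling (0.26 and 0.27). Th17 genes turned with a pseudocount of 10 (-0.026) and with CCLE and MLE counted as DLE (-0.056), and neutrophil genes turned without DLE 3 and healthy 1 (-0.10). With each dog left out, neutrophil genes ranged from -0.072 (without healthy 1) to 0.57, Th17 genes from -0.33 (without DLE 4) to 0.17 and melanocyte markers from -0.59 to 0.13 (without healthy 3). Spike-in scaling moved the pyoderma dog's count against healthy dogs from 75 to 49 probes. The pseudocount does not enter the edgeR count, and with the lowest probes left out the interferon, Th2, Th17 and melanocyte lists kept under 3 members and have no value. Counts near the background limit bound what can be told: 6 called falls lay at background in DLE dogs and 21 called rises lay at background in healthy dogs.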

Other observations

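The genes in this part were chosen after their values were seen, as was the test with the control row set as a block. KIT, the stem cell factor receptor, fell by 0.70 on the log2 scale in DLE skin (edgeR adjusted p = 0.0182) and MS4A2, a chain of the IgE receptor, fell by 0.68 (adjusted p = 0.0228). Neither was called under all 6 scalings, since reference gene scaling gave -0.017 for KIT and 0.068 for MS4A2, and the call of KIT ended without healthy dog 5 (-0.59) and that of MS4A2 without healthy dog 1 (-0.55). With the set as a block MS4A2 was called (log2 -1.54, adjusted p = 0.0181) and KIT was not (-0.05). MS4A2 took opposite positions in the single dogs, at 43.7 normalised counts in the MLE and 542 in the pyoderma dog, against 209 ± 51.6 (SD, n = 7) in DLE dogs. COL1A1, the main collagen of the dermis, fell by 1.17 in DLE, and EDA, the ectodysplasin signal of skin appendages, fell by 1.37. PTGER4, a prostaglandin E2 receptor, fell by 1.00 and PPARA, a nuclear receptor of lipid metabolism, fell by 1.08. None of these 4 falls was called with the set as a block or under all 6 scalings. The blocked log2 changes were -0.24 for COL1A1, -0.88 for EDA, -0.27 for PTGER4 and -0.525 for PPARA. The call of COL1A1 ended without healthy dog 2 (-0.80). That of PPARA ended without any 1 of DLE dogs 2, 4, 5 and 7 and healthy dogs 1 and 3 (-1.10 to -0.79). The cytokine IL10 (log2 0.06), CD38, an enzyme found on plasma cells (0.26) and the hypoxia factor HIF1A (0.44) were not called under TMM, but reference gene scaling called all 3 higher (0.74, 0.99 and 1.10) and panel median scaling called IL10 lower (-0.66), as did quantile scaling (-0.70).

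B2M, the light chain of MHC class I, averaged 108600 ± 17630 normalised counts in 7 DLE dogs against 41250 ± 8209 (SD) in 5 healthy dogs (log2 1.40 ± 0.30 SE, edgeR adjusted p = 0.00117; blocked 1.23, adjusted p = 0.0211). Its call ended under panel median scaling (log2 0.71, adjusted p = 0.0627). It was 1 of 17 probes higher in all 9 lupus dogs than in all 6 other dogs, with CD40LG, TNF, MS4A1 and KLRD1 as the other named ones, and 2 probes were lower in all of them. Lesional dogs of any diagnosis stood above all healthy dogs for 33 probes and below for 15, among them CCL27, CXCL12, EDA, PTGER4, FMO1 and CYP1B1. FMO1 lay at background in all but 1 DLE dog and 1 healthy dog, so its order carries no weight. Only CEACAM1 was higher in all dogs of set A than in all of set B, and ADRB1, CYP1B1 and the unnamed probe XM_545880.4 were lower. The melanocyte score lay below both the healthy and the DLE range in the MLE and pyoderma dogs (log2 -2.21 and -2.18 from the healthy mean). All 3 members lay below the background limit in both dogs, so these scores are upper bounds.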
